A study of Mus musculus with 2 samples.

How the data were processed

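Gene expression was measured in 2 three-dimensional murine skin models, 1 from an Itih5 knockout mouse and 1 from a wildtype control. The titles of both mark day 7. Per the labels' protocols, keratinocytes and fibroblasts were grown from the skin of adult mice and passaged repeatedly. Total RNA was isolated with a DNase step, amplified to sense-strand cDNA with the Ambion WT Expression Kit and labelled with biotin by the Affymetrix WT Terminal Labeling kit, per the labels. Each model was hybridised to 1 array. The scanner software, the summary of probes into probe sets and the normalization between the arrays are not given in the sources used here.

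The deposited values are probe set intensities on a linear scale, but the decimal point was missing from 67457 of the 67586 values. The other 129 values, with up to 2 decimals, had kept theirs. As written, the columns had a Pearson r of 0.04 across probe sets, which are not independent replicates. The design fixed before the data were examined assumed values that needed no such step. The point was therefore restored first, and the planned steps were run on log2 of the restored intensities. A place was accepted as possible if the number it gave was the shortest decimal form of a single-precision number, was a power of 2 with a single-precision log2 exponent, and lay between 18 and 20000. None of the 67457 values lacked a possible place, whereas 89.3% of random 8-digit numbers did. Of the 8714 values with 1 place by the single-precision form alone, 100% were such powers of 2, against 22.3% of random numbers of the same levels. For 21121 of the 33793 probe sets (62.5%) 1 place was possible on both arrays, and over these the log2 values had a Pearson r of 0.96 across probe sets.

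For the other probe sets, each pair of possible places was given a probability from the joint distribution of mean level and difference, learnt from all probe sets in 25 rounds of expectation maximisation with differences treated alike in both directions. Pairs with a probability of at least 0.95 were kept. This restored 31849 probe sets (94.2%), of which 55.6 are expected to be misplaced, and 1944 were left out as undecided. The allowed range and the minimum probability were set after the values were seen.

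The restoration was tested on 33793 simulated probe sets, 200 of them with a known change. Of all simulated probe sets, 93.7% were restored, and 27 of these (0.085%) were misplaced. Seeded changes of 1.2 and 2.0 log2 were restored in 52.0% and 46.0% of 50 cases each, with 0 misplaced. At 4.5 log2, 60.0% were restored and 5 of them were misplaced. At 3.3 log2, close to a shift of the point by 1 digit, 90.0% were restored and 22 of them (48.9%) were misplaced. Of 1663 simulated probe sets truly at least 2-fold apart, 61.6% were restored correctly. Of the 1029 restored as at least 2-fold apart, 4 were misplaced. Counts of genes at least 2-fold apart are therefore undercounts. A difference near 3.3 log2 can also be hidden where several places are possible, so a value near 0 is firm only for probe sets with 1 possible place. Among these, 21 (0.10%) were 8-fold to 12.5-fold apart.

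Probe sets were named through the platform annotation. Exactly 1 gene symbol was given for 23521 probe sets, several symbols for 1814, and 8458 were unnamed here. Of the probe sets with 1 symbol, 23328 had an Entrez identifier in a RefSeq table of assembly GRCm38.p6, and 0 symbols needed an update. Probe sets with several symbols were not used. Of several probe sets of a gene, the one with the highest mean was used. This gave 20798 genes. A gene counted as expressed if the higher of its log2 intensities reached the median level of all probe sets, 5.58 (intensity 47.8). Where one of a gene's values lies under this threshold, a fold depends on the background, and the intensities are given without one. The medians of the columns, 47.3 in the knockout model and 47.7 in the wildtype model, were close enough that no further normalization was applied. The 5th percentiles, 21.3 and 21.4, mark the background of the arrays.

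With 1 array per group there is no replicate error, no difference has a replicate check, and no p-value was computed. The number of arrays limits the precision. Genes were counted by size, at least 2-fold apart. For each of 43 gene and cell type lists, fixed before the data were examined, the median log2 difference of the expressed members was set among the medians of 10000 random lists of the same size matched on mean level in 20 bins. A list with a percentile under 2.5 or over 97.5 is said to stand apart, which describes these arrays only. Lists with under 5 expressed members are given by gene. On simulated differences, a list of 20 genes shifted by 0.5 log2 reached percentile 100.0, and 8 of 100 unshifted lists stood apart.

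The genes named in the text follow a rule fixed before the data were examined, except members of gene families and Col5a1 in the closing section, which were chosen after their values were seen. It takes Itih5, the 15 expressed genes with the highest and the 15 with the lowest difference (predicted genes and small RNAs left out), and up to 4 members of each list with and against its direction. It also takes all measured members of the inter-alpha-trypsin inhibitor, hyaluronan and sex-linked lists, list members under 2-fold where this is said, and expressed genes within 5 Mb of Itih5. Of the 30 ranked genes, 19 had 1 possible place, and the lowest probability among the genes named by the rule was 0.95. In all, 142 probe sets of list members were undecided, among them those of Acta2, Ccl2, Timp1, Krt16, Tgm1, Trp63, S100a8, Cemip, Ptx3 and Xist, and these have no value here.

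Alternatives covered the filter (none, the 75th percentile, or both values past the median), the normalization (medians centred, quantile, or loess with a span of 0.3), the threshold (1.5-fold and 3-fold), the summary of probe sets, a pseudocount of 16, the mean in place of the median, unmatched random lists and another random seed. Added after the values were seen were a minimum probability of 0.99, probe sets with 1 possible place only, and every probe set at its likeliest place. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.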

Results

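RNA of a three-dimensional skin model built from knockout mouse cells and of a wildtype model was compared on 1 array each, at day 7. The series concerns ITIH5, an inter-alpha-trypsin inhibitor heavy chain, as a stabilizer of hyaluronan in skin, and the comparison addresses how expression differs between models labelled knockout and wildtype. Values are array intensities with the decimal point restored, and differences are log2 values of the knockout minus the wildtype model. Intensities ran from 18.3 to 14117 in the knockout model and from 18.5 to 15400 in the wildtype model.

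Itih5 itself, the gene named by the genotype, was below the expression threshold in both models. Its 1 probe set (17366670, Entrez 209378) read 30.4 in the knockout and 29.8 in the wildtype model, a log2 difference of 0.03. Both values lay below the intensity of 47.8 that defined an expressed gene. The part of the gene that was removed is not given in the sources used here, so this probe set checks neither label. The related heavy chains Itih1, Itih2, Itih3 and Itih4 and the light chain gene Ambp were also below the threshold in both models. Tnfaip6, whose product transfers heavy chains onto hyaluronan, was the 1 expressed member of the inter-alpha-trypsin inhibitor list, with 93.4 in the knockout and 58.0 in the wildtype model, which is under 2-fold.

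Genes of the late epidermal programme were far lower in the knockout model, and genes of the fibroblast matrix were higher. Lce3e, a late cornified envelope gene, read 151 in the knockout and 6899 in the wildtype model, 45.6-fold lower. Klk14, a kallikrein protease of the shedding epidermis, was 36.2-fold lower, with 307 against 11121. In the other direction, Car4, a membrane-bound carbonic anhydrase, read 5434 in the knockout and 192 in the wildtype model, 28.2-fold higher. Fn1, which encodes fibronectin, was 4.09-fold higher, with 2910 against 712.

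Of 12439 expressed genes, 479 (3.85%) were at least 2-fold higher and 388 (3.12%) at least 2-fold lower in the knockout model. Differences of at least 8-fold were seen for 5 higher and 48 lower genes. Most genes differed little, with 80.3% within 1.5-fold, a median difference of 0.05 and a Pearson r of 0.93 across expressed genes, which are not independent replicates. Of the counted genes, 306 higher and 288 lower ones had 1 possible place of the decimal point, and 3.34 and 1.98 genes are expected to be misplaced.

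Besides Lce3e and Klk14, the 15 lowest genes were Lce3f (31.6-fold), Rptn (29.7-fold), Lce1b (41.6 against 1068) and Sprr3 (26.7 against 588) of the cornified envelope, the tight junction gene Cldn17 (28.5-fold), the protease inhibitor Serpinb12 (36.7 against 932), the calcium-binding Calm4 (23.9-fold), the keratin Krt13 (22.7-fold), the adhesion molecule Ceacam1 (21.0-fold), the chitinase Chit1 (37.1 against 711), the proteases Tmprss11a (47.4 against 868) and Cpa4 (18.3-fold), and Nccrp1 (16.8-fold). Krt13 read 118 in the knockout and 2666 in the wildtype model, and Ceacam1 181 against 3788. After Car4, the highest genes were Plac8 (16.4-fold), the oxidised LDL receptor Olr1 (421 against 40.0), the prostaglandin transporter Slco2a1 (9.91-fold) and Fstl1, a secreted follistatin-like glycoprotein (9.78-fold). They were followed by the enkephalin precursor Penk (7.95-fold), the gastrin-releasing peptide receptor Grpr (7.90-fold), Tnfrsf26 (7.61-fold), Pwwp3b (300.0 against 40.6), Brinp3 (7.38-fold), Fgl2 (7.31-fold), Tmem45a (7.24-fold), the serotonin receptor Htr2a (6.76-fold), Mlana (6.45-fold) and Prune2 (6.20-fold).

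**Figure D1:**
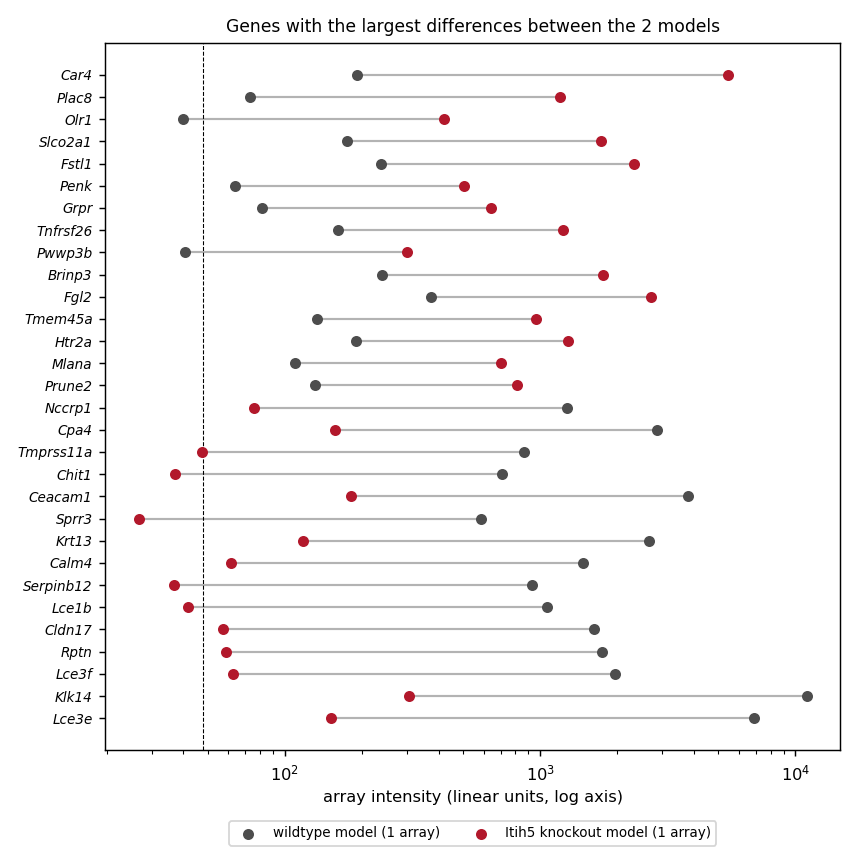
Array intensity, on a log axis, of the 15 genes with the highest and the 15 with the lowest difference in the knockout (red) and wildtype (grey) models, 1 array each; the dashed line is the intensity of 47.8 that defined an expressed gene. Car4 lies at 5434 in the knockout and 192 in the wildtype model, and Lce3e at 151 and 6899.

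Lists for the upper epidermis were lowest of all. Among 33 expressed cornified envelope and late differentiation genes, 25 were at least 2-fold lower and 0 at least 2-fold higher in the knockout model, with a median difference of -1.84 (3.58-fold), below all 10000 random lists (percentile 0.0). The 8 others were under 2-fold, among them Ivl, the involucrin gene, with 143 against 141 and several possible places of its point. These counts leave out undecided members, since 41 of the 50 with a probe set of their own were restored. At their likeliest places the undecided ones lay both higher and lower in the knockout model. Of 24 spinous and granular layer genes, 19 were at least 2-fold lower and 1 was at least 2-fold higher, with a median of -2.20 (4.60-fold) and percentile 0.0. Klk8 read 216 against 3152 and Klk13 106 against 1480, whereas the protease inhibitor Serpinb2 was 2.16-fold higher, with 3504 against 1621.

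Genes of the list for all keratinocyte layers were lower too. All 17 expressed members of that list were below 0, 8 of them at least 2-fold, with a median of -0.98 (1.97-fold) and percentile 0.0. They are the restored ones of 22 members with a probe set of their own. At their likeliest places most but not all undecided probe sets of this list read lower. The epithelial transcription factor genes Ovol1, Elf3 and Ehf were 5.00-fold, 3.88-fold and 3.26-fold lower. Ovol1 also belongs to the spinous and granular list. Of 12 basal keratinocyte genes, 3 were at least 2-fold lower, Dsg3 with 2150 against 6581, Krt14, the basal keratin, with 4076 against 9538, and Krt15 with 63.2 against 127. The list's median was -0.70 (1.63-fold) with percentile 0.0. Itga3 (571 against 567, with 2 possible places of its point) and Dst (469 against 322) did not read lower.

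Keratinocyte genes of wounds and hyperproliferation stood apart downward, with 7 of 15 at least 2-fold lower, a median of -0.91 and percentile 0.0. Il1f6, an interleukin-36 cytokine gene, read 1001 in the knockout and 6000 in the wildtype model, the gap junction gene Gjb2 675 against 3438, and Lcn2, under 2-fold, 9017 against 7115. Antimicrobial and defence genes went both ways, with 5 of 14 at least 2-fold lower and 2 higher (median -0.49, percentile 0.0). S100a7a read 185 against 1668 and Chil1 was 5.26-fold lower, while the acute phase gene Saa2 was 2.44-fold higher and Reg3g read 80.5 against 28.5, near background in the wildtype model. This list held 3 expressed genes in common with the wound list, and without the expression filter its median was 0.02, at percentile 50.3. Of 20 barrier lipid genes, 8 were at least 2-fold lower (median -0.21, percentile 0.88), among them the ceramide synthase gene Cers3 with 935 against 3947 and Sdr9c7 with 76.8 against 1037. With every probe set at its likeliest place this list reached percentile 2.79 and no longer stood apart.

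**Figure D2:**
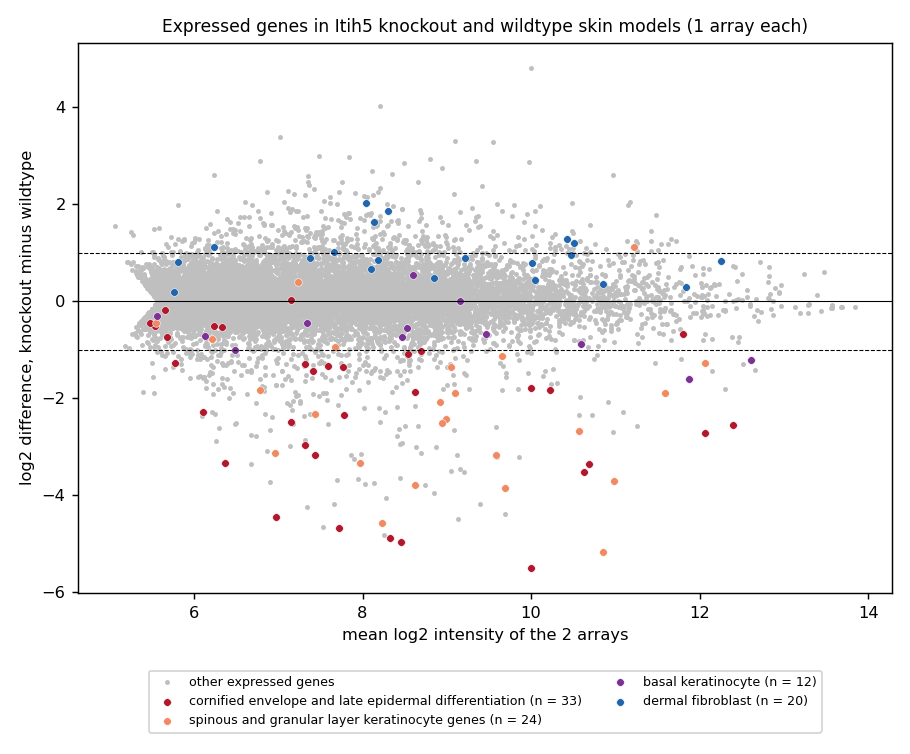
Log2 difference (knockout minus wildtype) of each expressed gene against its mean log2 intensity on the 2 arrays, with 4 lists coloured; dashed lines mark 2-fold. The 33 cornified envelope genes have a median of -1.84, the 24 spinous and granular genes -2.20, the 12 basal keratinocyte genes -0.70 and the 20 dermal fibroblast genes 0.86.

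Fibroblast and interstitial matrix genes were higher in the knockout model. All 20 expressed dermal fibroblast markers were above 0, 7 of them at least 2-fold, with a median of 0.86 (1.82-fold), above all 10000 random lists (percentile 100.0). The collagen gene Col1a1 read 2145 against 876 and the transcription factor gene Twist2 495 against 160. Of 25 genes for interstitial collagens and the enzymes that modify them, 11 were at least 2-fold higher and 0 lower, with a median of 0.89 (1.85-fold) and percentile 100.0. Loxl1, a lysyl oxidase of collagen and elastin crosslinking, was 4.09-fold higher, the lysyl hydroxylase gene Plod1 3.78-fold and Col6a2 3.61-fold, whereas P3h2 read 85.0 against 161. These lists shared 8 expressed genes, and the 8 fibroblast markers outside the matrix lists were also all above 0, with a median of 0.81.

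Among 31 proteoglycan, elastic fibre and matricellular genes, 8 were at least 2-fold higher and 1 lower (median 0.53, percentile 100.0). Fn1 was 4.09-fold and Tnc, the tenascin C gene, 3.43-fold higher, while the fibulin gene Efemp1 was 4.46-fold lower, with 187 against 835. Basement membrane genes had a median of 0.31 and percentile 98.8, with 3 of 23 at least 2-fold higher (Col4a2, Nid1 and Hspg2) and Fras1 2.42-fold lower. The laminin chain genes Lama3 (556 against 895) and Lamb3 (305 against 448) read lower, under 2-fold. The basement membrane list no longer stood apart without a filter (percentile 90.1), with 1 possible place only (96.3) or by its mean (94.4). Of 21 matrix proteases and inhibitors, 6 were at least 2-fold higher (median 0.51, percentile 99.99). Mmp19 was 3.36-fold and Mmp9 3.05-fold higher, against Mmp13, a collagenase, 2.47-fold lower with 3713 against 9158. Adam19 had differences of 2.46 and 0.94 on its 2 probe sets, with a mean over them of 1.70.

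Hyaluronan genes, the subject of the series, did not move together. Of 13 expressed members, 1 was at least 2-fold higher and 1 lower, and the median of 0.07 lay at percentile 56.8. These counts leave out Cemip and Layn, whose points were undecided. At their likeliest places Cemip read lower and Layn higher in the knockout model. Vcan, the hyaluronan-binding proteoglycan versican, read 653 in the knockout and 269 in the wildtype model (2.43-fold higher). The synthase gene Has3 read 165 against 376 (2.28-fold lower, with a probability of 0.95 for its place). Has2 (146 against 127) and Has1 (50.4 against 47.9) were close to equal. The hyaluronan receptor gene Cd44 read 1291 against 2445, and Ugdh, which supplies the precursor UDP-glucuronic acid, 1052 against 550, both under 2-fold. Hyal2 (347 against 269), Hyal3 (75.1 against 82.5), Cemip2 (238 against 190), Hmmr, Lyve1, Habp4 and Hapln3 were also under 2-fold.

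NF-kappaB targets had a median of 0.55 (percentile 99.98), with 4 of 18 at least 2-fold higher and 0 lower. Ptgs2, the inducible cyclooxygenase gene, read 1084 against 302 and Vcam1 327 against 113, while Nfkbiz (400.5 against 544) was lower, under 2-fold. Of 26 cytokines and chemokines, 5 were at least 2-fold higher and 3 lower (median 0.25, percentile 98.6). The alarmin gene Il33 read 1775 against 448 and Ccl7 1706 against 548, whereas Il18 read 50.9 against 194 and Cxcl9 41.3 against 136. With 1 possible place only, NF-kappaB targets lay at percentile 97.3 and cytokines at 95.4, and the cytokine list also lost its place without a filter (96.7) and by its mean (85.2).

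Markers of other cell types differed as well. Of 8 expressed adipocyte genes, 3 were at least 2-fold higher and 1 lower (median 0.55, percentile 99.8). Fabp4 read 4974 against 816 and Dgat2 426 against 1522. The other higher genes, Cd36 (83.9 against 33.5) and Lpl (84.7 against 42.3), were under the expression threshold in the wildtype model. Of 5 endothelial genes, Kdr was at least 2-fold higher at low levels, 87.4 against 36.1 (median 0.42, percentile 98.4), and this list did not stand apart without a filter (63.1) or against unmatched lists (94.9). Of 6 melanocyte genes, 2 were at least 2-fold higher, Mlana with 705 against 109 and Mitf with 464 against 215. The other 4 were under 2-fold, among them Sox10, lower at 51.3 against 66.4. The list did not stand apart by its median (percentile 83.0). The 7 expressed macrophage and Langerhans cell genes had a median of -0.30 and percentile 2.66, inside the range of random lists, and Cd14 was 2.29-fold higher. That median is the value of Epcam (954 against 1173), which also belongs to the all-layer keratinocyte list.

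**Figure D3:**
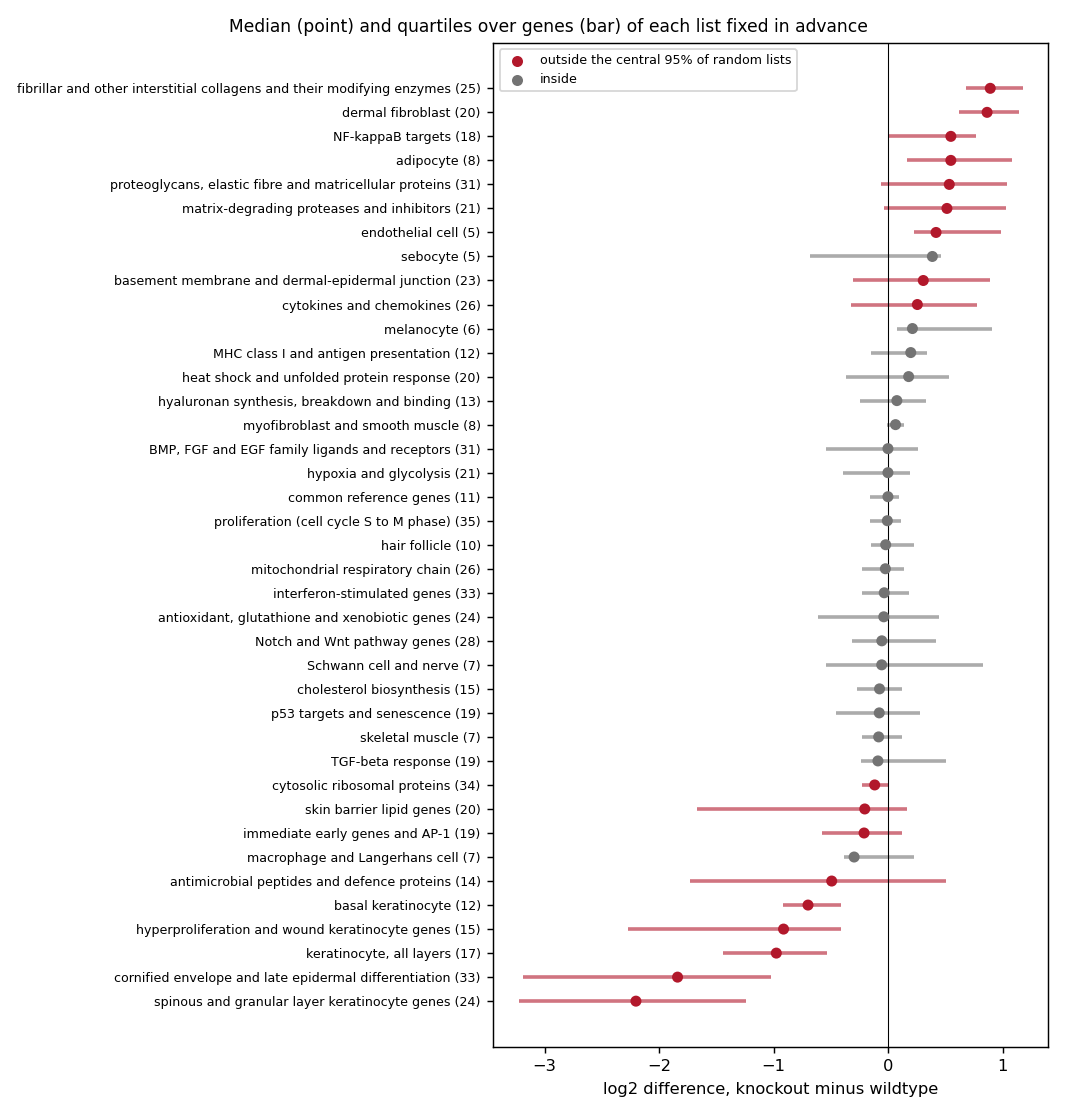
Median log2 difference (point) and quartiles over genes (bar), knockout minus wildtype, of the 39 lists with at least 5 expressed members, whose number stands in parentheses; red marks lists outside the central 95% of random lists. Medians run from -2.20 for spinous and granular layer genes to 0.89 for interstitial collagens.

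In all, 18 of the 39 lists with at least 5 expressed members stood apart, 9 lower and 9 higher. Chance would put 5% of independent lists there, 1.95 of 39, but these lists share members, and 8 of 100 simulated unshifted lists stood apart. Immediate early genes (median -0.21, percentile 1.04) and cytosolic ribosomal protein genes (median -0.12, percentile 2.15) completed the lower ones, and each lost its place under several settings. Klf4, a transcription factor gene of the differentiating epidermis, was the immediate early gene at least 2-fold lower, with 284 against 1062, and Egr2 was 2.06-fold higher. None of the 34 ribosomal protein genes reached 2-fold.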

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

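The settings with a minimum probability of 0.99, with 1 possible place and with every likeliest place were chosen after seeing the data. A threshold of 1.5-fold gave 1480 higher and 973 lower genes and one of 3-fold 119 and 169, by construction of the threshold. With 1 possible place only, 312 genes were higher and 289 lower, since fewer genes were tested. With every probe set at its likeliest place 701 were higher and 569 lower, against 479 and 388 in the main analysis, of which 478 and 386 were shared. The other settings gave 370 to 495 higher and 309 to 417 lower genes, and quantile normalization shared 451 and 388 with the main analysis. No gene below the expression threshold was 2-fold apart, so dropping the filter moved neither count. The Itih5 difference ranged from 0.02 to 0.04. Between 12 and 18 lists stood apart under the 12 settings. Of the lists standing apart in the main analysis, 10 did so under each setting that left them at least 5 expressed members. They included the 4 lists of cornified, spinous and granular, basal and all-layer keratinocyte genes. The others were those of wound keratinocytes, dermal fibroblasts, adipocytes, interstitial collagens, proteoglycans and matrix proteases. The adipocyte list was not checked with 1 possible place only, since too few of its members had one. Another 4 of the lists with a percentile in the main analysis stood apart under some other setting only. Melanocyte genes did so by their mean, and macrophage genes under quantile normalization or the pseudocount. Notch and Wnt genes did so under the stricter filter, and Schwann cell genes at every likeliest place. Lists too small for a percentile in the main analysis are not covered by this count. Of 451 list medians under alternatives, 53 moved and 1 reversed, that of antimicrobial genes without a filter (0.0213), where the cause was not tested. Of 1384 values of named genes under alternatives, 12 moved and 0 reversed. No paired analysis was possible because each group has 1 sample, and for the same reason no sample could be left out. Genes near the background of about 21.3 have compressed differences, and genes with several possible places are missing from the counts more often when they differ.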

Other observations

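The gene families described here, grouped by symbol, were chosen after their values were seen. Members with an undecided point are not counted in them. All 5 expressed desmosomal cadherins with a restored point were at least 2-fold lower in the knockout model (median -2.44), from Dsg1a at -3.35 to Dsc1 at -1.14. Of 11 kallikreins, 7 were at least 2-fold lower (median -3.14), while Klk4 stood at -0.05 and Klk1b24 at 0.59. Of 10 small proline-rich genes, 8 were at least 2-fold lower (median -1.93). Late cornified envelope genes of the Lce family (6 of 8 at least 2-fold lower, median -2.84) and Tmprss11 proteases (3 of 4, median -2.20) were lower too. In other families, 7 of 8 claudins (median -0.07), 2 of 3 connexins of the Gjb family (median -0.59) and 7 of 14 Serpinb genes (median -0.68) were under 2-fold, and of the other Serpinb genes 6 were lower and 1 was higher. Keratins were split, with 9 of 32 at least 2-fold lower, such as Krt23 at -3.79 and Krt10 at -1.35. Krt1 stood at -0.46, under 2-fold, and Krt8, a keratin of simple epithelia, was higher at 1.34. The interleukin-36 antagonist gene Il1f5 stood at -2.58 beside Il1f6 at -2.58. Of 23 Hox genes, 22 were under 2-fold and Hoxc6 was higher at 1.64. The medians of these families kept their sign under quantile and loess normalization.

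Several programmes did not stand apart as lists although single members differed. Of 31 BMP, FGF and EGF family genes, 4 were at least 2-fold higher and 4 lower (median -0.0033, percentile 27.8). The growth factor genes Fgf7 and Fgf10, made by mesenchyme, were 2.52-fold and 2.88-fold higher, while Hbegf was 4.58-fold and Bmp7 3.19-fold lower. Of 19 TGF-beta response genes (median -0.09, percentile 7.96), Bambi was 3.80-fold and Id1 2.25-fold lower, and Fn1 was 4.09-fold and Col1a1 2.45-fold higher. Of 28 Notch and Wnt genes (median -0.06, percentile 11.5), the Notch ligand gene Jag1 and Wnt4 were 2.08-fold and 2.06-fold lower and the Wnt antagonist gene Dkk3 2.70-fold higher. None of 35 proliferation genes with a restored point reached 2-fold (median -0.01, percentile 19.1), with Mki67 at 449 against 655. Bst2 was the 1 of 33 interferon-stimulated genes at 2-fold or more (median -0.04, percentile 18.3), Bnip3 the 1 of 21 hypoxia and glycolysis genes (median -0.0035, percentile 27.8), and Cdkn2a, higher at 425 against 206, the 1 of 19 p53 and senescence genes (median -0.08, percentile 12.3). Of 24 antioxidant genes (median -0.04, percentile 17.6), Gsta4 and Gsta3 were 2.43-fold and 2.39-fold lower and Aldh1a1 and Gstt1 3.13-fold and 2.02-fold higher.

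The remaining lists lay inside the range of random lists. No member reached 2-fold among genes of cholesterol synthesis (percentile 14.1), MHC class I (88.1), heat shock and unfolded protein response (84.5), the respiratory chain (20.1), myofibroblasts (61.2), hair follicle (38.0) and skeletal muscle (28.6). Cidea, 5.17-fold lower, was the exception among sebocyte genes (percentile 92.4) and Gusb, 2.39-fold higher, among common reference genes (percentile 36.2). Median intensities in the knockout and wildtype models were 55.7 and 57.2 for myofibroblast genes and 58.8 and 55.2 for hair follicle genes. For skeletal muscle genes they were 61.0 and 66.3. Such levels lie close to the expression threshold, and differences near the background are compressed. The myofibroblast, hair follicle and skeletal muscle lists are therefore not shown to be unchanged. The cholesterol, MHC class I, heat shock and respiratory chain lists lack undecided members, so they are not shown to be unchanged either. Of myofibroblast genes, Acta2 was undecided. Schwann cell and nerve genes (percentile 30.5) held Pmp22 and Ncam1, 4.04-fold and 3.23-fold higher, and Cdh19, near background in the knockout model against 80.6 in the wildtype model. The 2 expressed T cell and mast cell genes, Tpsab1 and Kit, and the 3 expressed histone genes, H2bc3, H1f5 and H1f2, were under 2-fold. Of the Y-linked genes, Uty read 28.2 in the knockout and 210 in the wildtype model, Kdm5d 274 against 193, and Eif2s3y, Sry, Usp9y and Zfy2 were below the expression threshold in both models. Uty and Kdm5d went opposite ways and Xist was undecided, so these values do not settle whether the mice were of the same sex.

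The tests on cornified and on spinous and granular genes below were chosen after values of some member genes had been seen, and the test on genes near Itih5 was chosen before. Lower cornified envelope genes, median -1.84, are the first pattern. The tables argue against normalization between the arrays as the cause, since the list's highest median under quantile and loess was -1.85, and against misplaced decimal points, since the 18 members with 1 possible place had a median of -2.09. Fewer keratinocytes relative to fibroblasts would lower the genes of all layers alike, provided that these genes were expressed in keratinocytes alone. Cornified genes lay below all-layer keratinocyte genes by a difference of -0.86, with a bootstrap interval over genes of -1.90 to 0.07, and below basal genes by -1.14 (-2.02 to -0.49), so for them this cannot be told apart from a change within the keratinocytes. For spinous and granular genes the differences were -1.22 (-2.16 to -0.37) and -1.50 (-2.42 to -0.72), so they lay below both keratinocyte lists. The all-layer list shares Ovol1 with the spinous and granular list. The intervals treat genes as independent and the compared genes as read from keratinocytes alone, but Dst and Itga3 of the basal list did not read lower. A smaller share of keratinocytes is therefore not excluded for spinous and granular genes either, and no biological explanation was tested.

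The fibroblast markers ranged from 0.18 for Col5a1 to 2.03 for Loxl1, and another probe set of Col5a1 was left out as undecided. Both models were built from fibroblasts and keratinocytes, so these markers belong to the models themselves, and no value here separates a larger share of fibroblasts from higher expression within them.

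Genes beside Itih5 are the other pattern. DNA of the targeted stem cell line that stays around a targeted gene may bring differences of its own, in which case genes within 5 Mb should differ more than others. The median absolute difference of 34 expressed neighbours, placed by assembly GRCm38.p6, was 0.28 against 0.25 in matched random lists, percentile 74.2, so no excess was seen. Camk1d was 2.17-fold lower and 5031426D15Rik read 59.2 against 29.2. The test leaves open an effect on single neighbours, and the origin of the knockout line is not given in the sources used here.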
